A study of Mus musculus with 16 samples.

How the data were processed

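RNA was measured in epididymal white adipose tissue, the visceral fat pad attached to the epididymis, of male C57BL/6 mice made obese by 20 weeks of high-fat diet. Per the labels' protocols, total RNA was isolated with Trizol, treated with DNase and purified on RNeasy columns. The authors deposited 1 table of FPKM values (fragments per gene, scaled by the length of the gene and the depth of the library) for 16 libraries. The aligner, the counting tool, the genome build and the library kit are not given in the sources used here. All 16 columns matched a sample by title, and 0 columns had no sample. The series' design line also speaks of inguinal fat, which was not analysed here.

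The 4 groups of 4 libraries were taken from the labels: vehicle and tubastatin (tubastatin A, an inhibitor of the deacetylase HDAC6), both from mice aged 25 weeks, and AdKO (adipose-specific Hdac6 knockout) and AdCre (adiponectin-Cre controls), both from mice aged 28 weeks. The labels also give all 8 vehicle and tubastatin animals the genotype of a global HDAC6 knockout, while the series' design line names no knockout for them and gives about 28 weeks, the age labelled for the knockout cohort. This conflict was not resolved, so the genotype and the age behind the drug comparison are uncertain. The labels do not say outright that each library is a separate animal, so p-values measure the spread between these libraries.

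The table held 54532 Ensembl gene IDs, of which 54409 had a symbol in the reference names and 21760 were at 0 in every library. Low FPKM values moved in whole-number steps. With exon-union gene lengths from GENCODE M21 (GRCm38), 96.3 to 96.5% of the values above 0 in each library came out as whole reads within 0.01 read, and 12622 of the tested genes (95.1%) did so in all 16 libraries. The depth recovered in this way was 18234386 to 24776803 reads per library. How reads were assigned between near-identical copies (histone and tubulin genes, T cell receptor segments) and whether strand was used are not given in the sources used here, so values of such genes and of overlapping genes are uncertain. Coordinates are those of GENCODE M21, which is the annotation used here and not a build stated by the authors.

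Genes with a mean FPKM of at least 1 over the 16 libraries (13271 genes) were tested on log2(FPKM + 1) with limma-trend (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates changes of low genes. Each comparison used its own 8 libraries, and the difference between the drug and knockout effects used all 16. Gene lists (46 lists of pathway and cell type genes, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, with fry beside it. The 43 lists with at least 3 tested members entered. Hdac6 was tested within each cohort by a two-sided exact permutation test over 70 relabelings, and so were list levels. A list level is the mean over its tested members of log2(FPKM + 1), each gene centred on its mean over the 16 libraries.

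The genes named in the text follow a rule fixed before the data were examined. It takes Hdac6, Lep, Adipoq and Ucp1 always, then the 10 largest changes per direction among called genes whose groups do not overlap. Where fewer than 10 genes are called it takes the 10 with the smallest p, with values only. It adds up to 4 members, smallest p first, of each list that passes camera or has 3 or more called members. Predicted genes and clone names are left out. Socs3, the genes called with 1 shared spread, epithelial genes and genes of the cohort comparison were chosen after their values were seen.

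The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, median-of-ratios factors, TPM, quantile normalization, array weights, no trend, a robust prior, 1 spread shared by all 16 libraries, the replicate number as a block, and each library left out. Alternatives chosen after seeing the data were limma voom on the recovered reads, and AdCre replicates 2 and 3 left out together. The design set no test between the cohorts for Hdac6. A comparison of vehicle with AdCre was nevertheless added after the data were seen, and it stands apart among the closing observations.

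The gene tests were checked on simulated reads for 12622 genes, with 50 genes changed at each of 4 fold sizes. The reads were drawn from the real depths, each gene's mean over all 16 libraries and 1 spread per gene pooled over both cohorts. In the tubastatin comparison, limma-trend recovered 25 of 50 at 1.5-fold, 35 at 2-fold, 43 at 3-fold and 45 at 4-fold. For AdKO against AdCre the counts were 20, 38, 41 and 43, and for the difference of the effects 19, 28, 43 and 44. False calls numbered 11, 9 and 10 in these 3 runs. The simulated genes vary independently, unlike genes in tissue. Their spread was the same in both cohorts, while the median SE of the real fold changes was 0.0894 with tubastatin and 0.117 in AdKO. The counts are therefore not the share of changes that each real comparison would find. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.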

Results

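The series holds 16 RNA-seq libraries of epididymal fat from obese male mice, in 2 cohorts of 8. The first cohort compares 4 libraries of mice given tubastatin A, which blocks the catalytic activity of HDAC6, with 4 of mice given vehicle. The second compares 4 libraries with adipose-specific loss of Hdac6 (AdKO) with 4 adiponectin-Cre controls (AdCre). Depth was 19148810 to 21906045 reads in vehicle, 19969964 to 24776803 in tubastatin, 19072729 to 20834569 in AdKO and 18234386 to 22306236 in AdCre (4 libraries each). No libraries within a group agreed within sampling noise, with chi-square values per gene of 15.5 to 122 between them.

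Hdac6, the cytoplasmic deacetylase targeted in both cohorts (ENSMUSG00000031161, chromosome X, 7930120 to 7947889 in GRCm38), was read in every library. It stood at 1.41 to 1.78 FPKM in vehicle and 1.44 to 1.70 in tubastatin, and at 3.64 to 4.74 in AdCre and 2.66 to 4.11 in AdKO. The tubastatin mean of 1.56 ± 0.112 FPKM did not differ from the vehicle mean of 1.58 ± 0.167 by more than the spread (SD, n = 4, exact permutation p = 0.857). In the libraries labelled AdKO, Hdac6 was at 3.43 ± 0.595 FPKM against 4.17 ± 0.450 in AdCre, 17.7% lower, and the groups overlapped (SD, n = 4, exact permutation p = 0.0571, where the smallest possible is 0.0286). The log2 difference was -0.23, and -0.14 without AdKO replicate 2. Whole-gene RNA of the tissue also holds transcripts of other cells and does not show whether an exon was removed, so it neither bears out nor contradicts the AdKO label. The labels call the vehicle and tubastatin animals global knockouts, and 164 to 245 reads of Hdac6 were recovered in each of those libraries. Such reads do not show whether an exon was removed, so they do not settle that label either. The vehicle mean was 62% below that of AdCre, in a comparison that was not planned and is described among the closing observations.

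**Figure D1:**
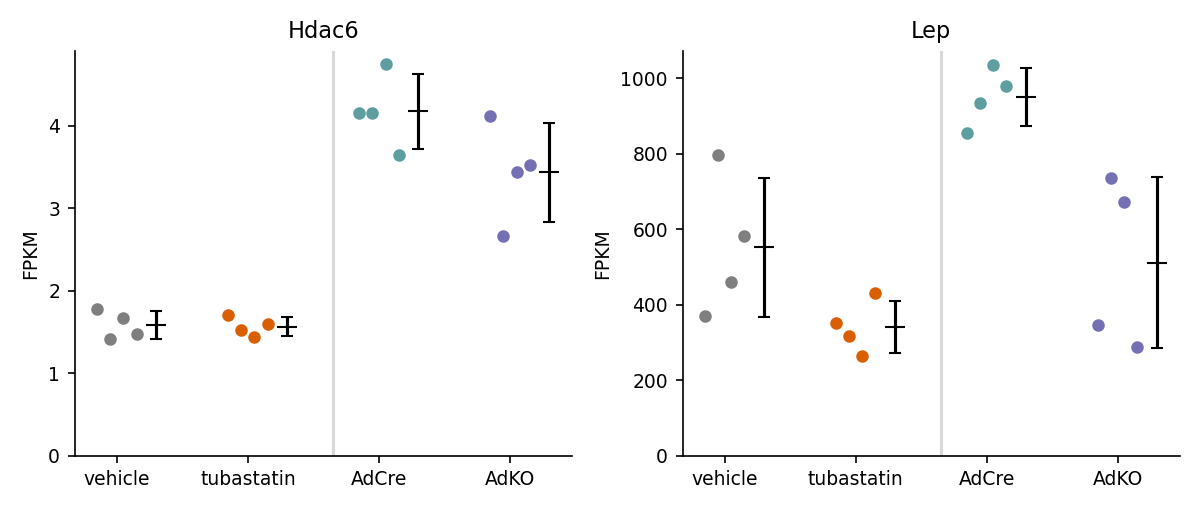
FPKM of Hdac6 (left) and Lep (right) in each library of the 4 groups, with points for libraries and black marks for the mean and SD (n = 4). Hdac6 overlaps between AdKO and AdCre, and Lep lies at 288 to 737 in AdKO, below the AdCre libraries at 855 to 1035.

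The first comparison asks how epididymal fat differs after the HDAC6 inhibitor. Of the 43 lists tested, the circadian clock list had the most members passing when adjusted over the list alone. Nfil3, a repressor of clock output genes, stood at 8.69 ± 1.93 FPKM with tubastatin against 3.08 ± 0.811 with vehicle, and Arntl, a core clock activator, at 2.04 ± 0.339 against 1.06 ± 0.203 (SD, n = 4 each). Dbp, a clock output factor, stood at 16.6 ± 3.12 against 28.4 ± 3.13 FPKM, and Tef at 19.6 ± 2.70 against 26.6 ± 2.19. None of these 4 genes overlapped between the groups. Their log2 fold changes were 1.25 (SE 0.18), 0.56 (SE 0.11), -0.75 (SE 0.13) and -0.43 (SE 0.10), with limma adjusted p-values over all genes of 0.153 to 0.269. Of the 16 tested clock genes 0 passed over all genes and 13 passed when adjusted over the list alone, 11 lower and 2 higher. The list passed camera (mean log2 fold change -0.18, adjusted p = 0.000558), with adjusted p = 0.819 with an estimated correlation. Its level did not overlap between the groups (exact permutation p = 0.0286, the smallest possible, and 0.307 adjusted over 43 lists). The neutrophil, tubulin and immediate early lists had the same exact p, also without overlap.

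**Figure D2:**
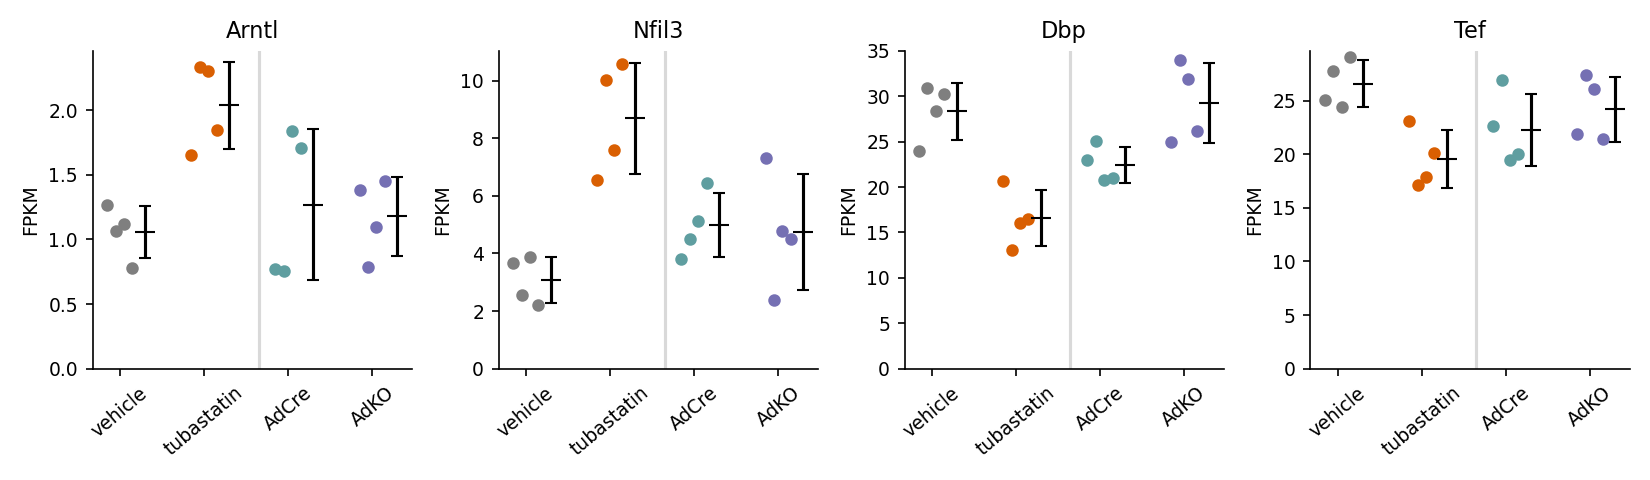
FPKM of the clock genes Arntl, Nfil3, Dbp and Tef, with points for libraries and black marks for the mean and SD (n = 4 per group). Arntl and Nfil3 are higher and Dbp and Tef lower in all 4 tubastatin libraries than in any vehicle library, while AdKO and AdCre overlap for all 4 genes.

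Camera called 16 of 43 lists, 6 higher and 10 lower with tubastatin, and 0 lists by fry or with an estimated correlation, where every list had an adjusted p of 0.731 or more. Neutrophil markers were higher (mean log2 fold change 0.77, adjusted p = 0.731 with an estimated correlation), and 5 of 6 members passed when adjusted over the list alone. The mean was 1.22 with a pseudocount of 0.1 and 0.479 with no filter on low values, and the call stayed. S100a8 stood at 8.77 ± 0.824 against 5.51 ± 1.57 FPKM and Retnlg at 1.89 ± 1.10 against 0.150 ± 0.152. Tubulin genes were higher by 0.13 on average (adjusted p = 0.731 with an estimated correlation), with 4 of 12 passing over the list alone. They were Tubb4a (log2 fold change 0.51, SE 0.08), Tuba4a (0.55, SE 0.09), Tubb2b (0.47, SE 0.09) and Tubb3 (0.68, SE 0.18). Inflammatory cytokine genes averaged 0.34 higher (median 0.21, 18 of 20 positive, 1 passing over the list alone), with Ccl12 at 19.1 ± 9.96 against 3.57 ± 2.06 FPKM and Tlr2 at 14.5 ± 1.47 against 10.9 ± 1.66. Nos2, of the same list, stood the other way at 0.831 ± 0.157 against 1.57 ± 0.527 FPKM, without overlap (log2 fold change -0.47, limma adjusted p = 0.343). Immediate early genes averaged 0.20 higher (13 of 16 positive, 2 passing over the list alone), with Fosl2 at 12.4 ± 1.96 against 7.97 ± 1.10 FPKM and Ier3 at 17.8 ± 5.61 against 8.32 ± 2.59. Egr2 stood the other way at 9.01 ± 0.377 against 11.4 ± 1.82 FPKM, without overlap (log2 fold change -0.30, limma adjusted p = 0.354). The cell cycle list averaged 0.15 higher, and these 3 lists had adjusted p = 0.819 with an estimated correlation.

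Extracellular matrix genes averaged 0.47 higher with tubastatin (adjusted p = 0.819 with an estimated correlation), with 0 of 26 members passing by either adjustment. Timp1 stood at 75.0 ± 46.6 against 23.9 ± 7.77 FPKM, and tubastatin replicate 1 had the lowest matrix level of the 8 libraries (-0.53). T and NK cell genes averaged -0.495 (Cd8a at 1.40 ± 0.325 against 3.04 ± 0.989 FPKM), B and plasma cell genes -0.66 and mast cell genes -0.36. Adipocyte identity genes averaged -0.29, lipogenesis -0.25, lipolysis -0.23, the TCA cycle and branched-chain amino acid list -0.13, fatty acid oxidation -0.12 and oxidative phosphorylation -0.08, and 0 members of these 6 lists passed when adjusted over the list alone. The lipogenesis member with the smallest p, Elovl5, had a positive log2 fold change (0.15). The adjusted p of these 9 lower lists was 0.819 to 0.841 with an estimated correlation. Vehicle replicate 2 had the highest adipocyte level of its cohort (0.32, against -0.08 or less in the other 7 libraries). Without it these 6 lists lost their calls (-0.144, -0.098, -0.10, -0.017, -0.022 and -0.022 in that order), as did the cytokine (0.272), cell cycle (0.061) and immediate early (0.136) lists, and 7 of the 16 lists stayed called. Tubulins lost the call without vehicle replicate 3 (0.109) or tubastatin replicate 3 (0.118), and mast cells without vehicle replicate 1 (-0.333) or 4 (-0.181) or tubastatin replicate 2 (-0.193). Fatty acid oxidation lost it without tubastatin replicate 1 (-0.104), and lipogenesis (-0.198), the TCA cycle list (-0.095) and cell cycle (0.103) without tubastatin replicate 3. Without vehicle replicate 1 fatty acid oxidation was at -0.198 and cell cycle at 0.245. The matrix, clock, T and NK cell, B cell and neutrophil lists stayed called by camera (preset correlation) with each library left out in turn. Yet T and NK cells were at -0.309 and B cells at -0.387 without vehicle replicate 3, and matrix at 0.723 without tubastatin replicate 1. The levels of the matrix, T and NK cell and B cell lists overlapped between the groups, unlike those of the clock and neutrophil lists. Their exact permutation p was 0.143 for matrix, 0.143 for T and NK cells and 0.171 for B cells. Adjusted over all lists tested, these were 0.512, 0.512 and 0.525. Other ways of splitting the same 8 libraries gave up to 21 lists.

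Lep, which encodes the satiety hormone leptin (chromosome 6, 29060220 to 29073877 in GRCm38), had 341 ± 69.4 FPKM with tubastatin and 553 ± 185 with vehicle, a log2 fold change of -0.66 (SE 0.24, limma adjusted p = 0.381). Adipoq, which encodes adiponectin, differed by -0.10 (SE 0.20, adjusted p = 0.846). Ucp1, the uncoupling protein of thermogenic fat, was at 0 to 0.644 FPKM in the 16 libraries and was not tested. The 10 genes with the smallest p had adjusted p-values of 0.128 to 0.153. Among them were the linker histone gene Hist1h1c (log2 fold change 0.54, SE 0.06), the retinol dehydrogenase gene Rdh10 (0.91, SE 0.12), Fbxo2 (1.42, SE 0.18), Pfn2 (0.63, SE 0.09), Tmem38a (0.43, SE 0.06), Fbxl16 (0.63, SE 0.08), Hist1h2bj (-0.66, SE 0.09) and the ribosomal RNA transcription factor gene Ubtf (-0.36, SE 0.05). Ndrg4 stood at 5.25 ± 1.15 against 2.09 ± 0.216 FPKM. In the list of leptin and JAK-STAT signalling genes 0 of 15 members passed over all genes and 1 passed when adjusted over the list alone. It was Socs3, a feedback inhibitor of leptin and cytokine receptors, at 24.0 ± 6.08 against 9.58 ± 1.98 FPKM (log2 fold change 1.22, SE 0.21, limma adjusted p = 0.179).

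Over all genes no single gene passed. Limma-trend called 0 of 13271 genes, with 1597 at an unadjusted p under 0.05 where 664 are expected by chance, and limma voom on the recovered reads called 0 with 1556. The smallest adjusted p was 0.128. The groups did not overlap for 949 genes (7.15%), where chance gives 2.86%. Both chance figures are averages, and other splits of the same libraries gave up to 1456 genes at an unadjusted p under 0.05. The count without overlap was not set against the splits. With 1 spread shared by all 16 libraries 8 genes were called, and without tubastatin replicate 1 or 2 the count was 2 or 1.

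The second comparison asks how the libraries labelled with loss of Hdac6 in fat cells differ from adiponectin-Cre controls. Cholesterol synthesis genes were lower in AdKO together. All 18 tested members had a negative fold change (mean log2 fold change -0.61), 0 passed over all genes and 15 passed when adjusted over the list alone. Dhcr7 stood at 5.05 ± 0.813 against 8.80 ± 0.847 FPKM, Mvd at 7.82 ± 1.15 against 11.2 ± 0.397, Cyp51 at 7.13 ± 1.66 against 12.3 ± 1.89 and Msmo1 at 4.68 ± 0.603 against 6.64 ± 0.718, without overlap. The list level did not overlap between the groups (n = 4 each, exact permutation p = 0.0286, the smallest possible, and 0.246 adjusted over 43 lists). In all, 5 of 43 lists had this exact p without overlap. The others were the interferon and thermogenic lists, and HDAC6 substrates and partners (-0.097) and Schwann cell genes (-0.11), which camera did not call. The cholesterol list passed camera (adjusted p = 3.93e-14), with adjusted p = 0.585 with an estimated correlation.

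Interferon response genes were higher in AdKO, with 18 of 19 members positive (mean log2 fold change 0.47), 0 passing over all genes and 12 when adjusted over the list alone. Isg15 stood at 22.1 ± 4.52 against 10.3 ± 2.13 FPKM, Oasl2 at 12.6 ± 2.01 against 6.62 ± 0.925, Irf7 at 12.4 ± 0.783 against 7.64 ± 1.19 and Gbp3 at 14.4 ± 0.928 against 8.96 ± 2.01. The list level did not overlap (n = 4 each, exact permutation p = 0.0286, and 0.246 adjusted over 43 lists), and the list passed camera (adjusted p = 1.26e-12), with adjusted p = 0.585 with an estimated correlation. Transcripts of epididymal epithelium were read in AdCre replicate 2 (Gpx5 at 5.97 and Adam7 at 1.91 FPKM). In AdCre replicate 3 Adam7 was at 5.57 and Epcam, a general epithelial gene, at 22.8 FPKM, but Gpx5 was at 0.0803. Without both of these libraries, an alternative chosen after seeing the data, the mean differences were -0.60 for cholesterol genes and 0.50 for interferon genes.

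**Figure D3:**
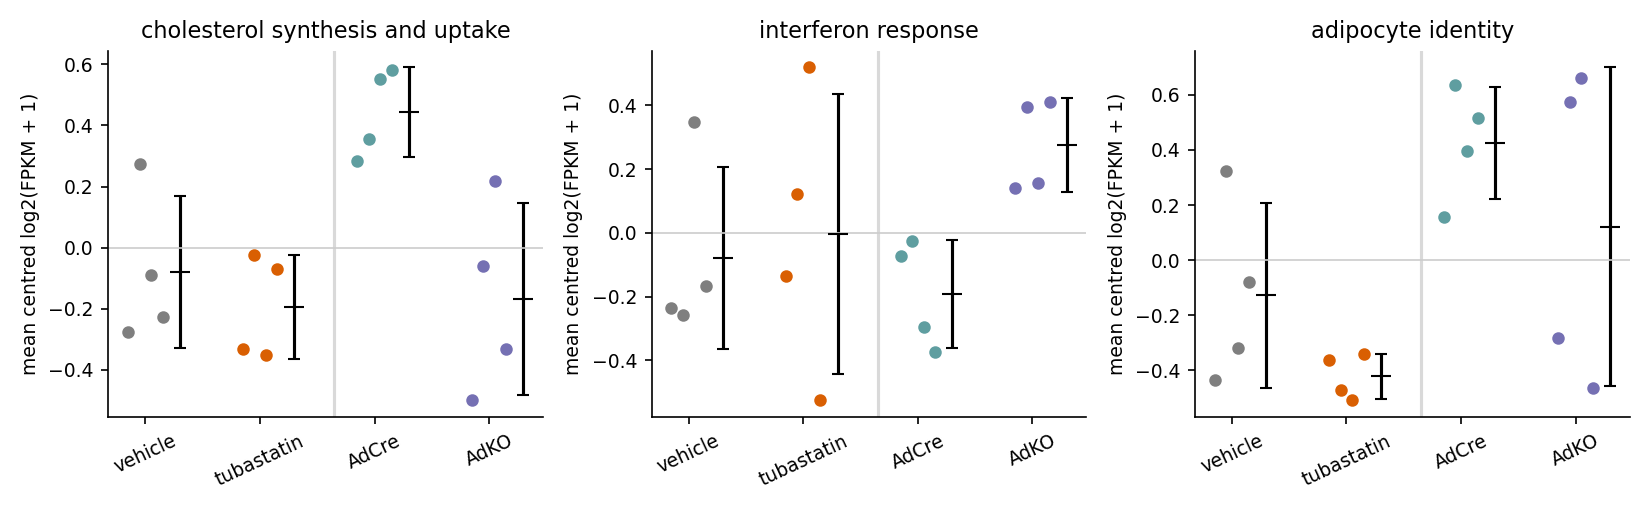
Level of the cholesterol, interferon and adipocyte identity lists in each library, as the mean over members of log2(FPKM + 1) centred on the 16 libraries, with points for libraries and black marks for the mean and SD (n = 4). The 4 AdKO libraries lie below all AdCre libraries for cholesterol genes and above them for interferon genes, while adipocyte genes are at -0.28 and -0.46 in AdKO replicates 1 and 4 and at 0.57 and 0.66 in replicates 2 and 3.

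Camera called 17 of 43 lists in AdKO, 6 higher and 11 lower, and 0 by fry or with an estimated correlation, where every list had an adjusted p of 0.585 or more. Mesothelial markers were higher (mean log2 fold change 0.62, adjusted p = 0.585 with an estimated correlation), with 6 of 12 passing over the list alone, including Lrrn4 at 13.6 ± 3.11 against 6.21 ± 1.53 FPKM, Wt1 at 7.87 ± 1.71 against 3.82 ± 1.18 and Upk1b at 21.4 ± 5.78 against 10.3 ± 2.90. Neutrophil markers averaged 1.41 higher and 3 of 6 passed over the list alone, with S100a9 at 39.8 ± 33.4 against 3.23 ± 2.78 FPKM. Their level was 2.11 and 1.74 in AdKO replicates 3 and 4 and -0.38 in replicate 2. T and NK cell genes averaged 0.485, B and plasma cell genes 0.509 and macrophage genes 0.335 higher. Thermogenic genes averaged -0.54, with 3 of 9 passing over the list alone (Otop1 at 2.88 ± 1.03 against 7.19 ± 1.96 FPKM). Fatty acid oxidation genes averaged -0.34, the TCA cycle list -0.29, oxidative phosphorylation -0.20 and lipogenesis -0.51, with 29 of 30 oxidative phosphorylation genes negative. The antioxidant, endothelial, lipolysis, adipocyte identity and angiogenesis lists averaged -0.14, -0.19, -0.28, -0.30 and -0.11. With an estimated correlation the adjusted p of these lists was 0.585 to 0.746. Leaving out a library ended the call of 6 lists. Adipocyte identity lost it without AdKO replicate 1 (-0.169) or 4 (-0.109), and lipolysis without AdKO 1 (-0.18), AdKO 4 (-0.104) or AdCre 4 (-0.241). Angiogenesis lost it without AdKO 4 (-0.077) or AdCre 4 (-0.066), and macrophages without AdKO 1 (0.163) or AdCre 3 (0.209). Endothelial cells lost it without AdKO 4 (-0.087), AdCre 2 (-0.121) or AdCre 4 (-0.13), and B cells without AdKO 1 (0.421), AdKO 3 (0.446), AdKO 4 (0.219), AdCre 1 (0.249) or AdCre 4 (0.314). Where the call stayed, values moved by over 1.5 times for several lists, with T and NK cells at 0.283 and the TCA cycle list at -0.189 without AdKO 4, lipogenesis at -0.32 without AdKO 1, adipocyte identity at -0.484 without AdKO 3, and B cells at 0.949 without AdKO 2 and 0.782 without AdCre 3. The B cell call was also lost with a pseudocount of 0.1 (0.62, camera adjusted p = 0.0631) and with median-of-ratios factors (0.509, camera adjusted p = 0.0566). Without AdCre replicates 2 and 3 together 13 lists were called, 12 of the 17 and lipid-associated macrophages. The lists lost were adipocyte identity (-0.215), lipolysis (-0.238), antioxidant (-0.107), macrophages (0.192) and endothelial cells (-0.157), while T and NK cells were at 0.753 and B cells at 1.19. T and NK cells were at 0.735 with a pseudocount of 0.1, and thermogenic genes at -0.295 with no filter on low values. Other ways of splitting the same 8 libraries gave up to 21 lists.

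**Figure D4:**
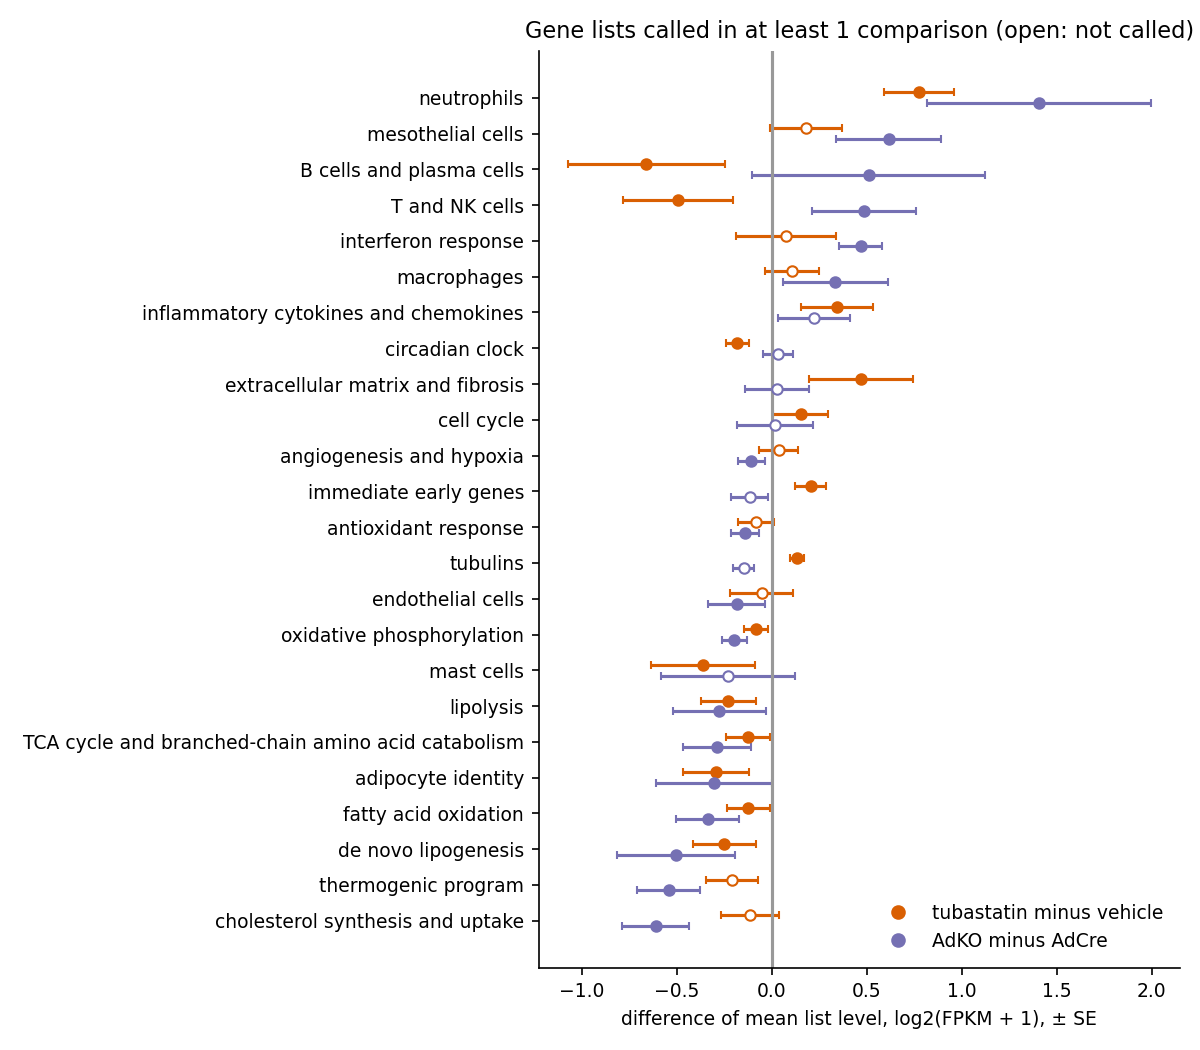
Difference of mean list level, on the log2(FPKM + 1) scale, for lists called by camera in at least 1 comparison, with filled points for called lists, open points for the others and bars for the SE over libraries (n = 4 per group). Neutrophil genes lie at 0.77 with tubastatin and 1.41 in AdKO, and cholesterol genes at -0.12 and -0.61.

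Lep stood at 511 ± 227 FPKM in AdKO, with 347 and 288 in replicates 1 and 4, where adipocyte genes were lowest, and at 951 ± 75.7 in AdCre, without overlap (log2 fold change -1.01, SE 0.31, limma adjusted p = 0.353), and Adipoq differed by -0.13 (SE 0.28, adjusted p = 0.864). The 10 genes with the smallest p had adjusted p = 0.191. They included Gata5, a transcription factor gene (log2 fold change 1.09, SE 0.14), Cxadr (1.09, SE 0.15), Prr15 (1.09, SE 0.16), Zc3h12a, which encodes an RNase that limits inflammatory transcripts (0.55, SE 0.09), Rn7sk (1.09, SE 0.13), Art2a-ps (-1.12, SE 0.15), the electron transfer flavoprotein gene Etfb (-0.98, SE 0.15) and Dhcr7, the last enzyme of cholesterol synthesis (-0.70, SE 0.11). Cd163l1 stood at 3.59 ± 1.51 against 0.564 ± 0.184 FPKM.

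Over all genes no single gene passed here either. Limma-trend called 0 of 13271 genes, with 1452 at an unadjusted p under 0.05 where 664 are expected by chance, and limma voom on the recovered reads called 0 with 1328. The smallest adjusted p was 0.191, and 860 genes (6.48%) did not overlap, where chance gives 2.86%. Both chance figures are averages, and counts vary widely around them when genes move together. In 6 of 35 splits of the same libraries, the real one included, as many as 1452 genes were reached, with 2479 as the highest other. The count without overlap was not set against the splits, so no excess over chance is shown. With 1 spread shared by all 16 libraries 43 genes were called, 19 higher and 24 lower, and without AdKO replicate 2 or 3 the count was 1.

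The design also allows the drug effect and the knockout effect to be set against each other, but only across cohorts. The cohorts differ in labelled genotype and labelled age, so drug against knockout cannot be told apart from cohort. Whether the drug was given to animals that lack Hdac6, as their labels say, is also unresolved. Limma-trend called 0 genes for the difference of the effects, with 1198 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0882, and limma voom called 0 with 1098. Array weights gave 6 genes, and 4 or 5 were called without tubastatin replicate 1 or AdKO replicate 2. Across genes, which are not independent replicates, the fold changes of the 2 comparisons correlated with Pearson r = 0.142 and Spearman rho = 0.217, and 57.6% had the same sign. Of 100 draws with labels shuffled within cohorts, 31 gave a Pearson r and 27 a Spearman rho at least as far from 0, so neither exceeded what relabeled libraries give. Without vehicle replicate 2 the Pearson r was -0.005. The overlap of called genes was 0, since neither comparison called any.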

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

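The counts of splits were tests fixed before their results were seen, and all other tests of explanations here were chosen after the list levels per library had been seen.

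Whether chance alone can group the libraries this way was tested by splitting the same libraries otherwise. For tubastatin against vehicle, the count of 1597 genes at an unadjusted p under 0.05 was reached by 1 of 35 splits, the real one, with 1456 as the highest other. For the 16 called lists, 13 of the 35 splits gave as many, with a highest other of 21, so chance is not excluded for the number of lists. For AdKO against AdCre, 6 of 35 splits gave as many as 1452 genes (highest other 2479), and 13 of 35 gave as many as 17 lists (highest other 21), so chance is not excluded for either. A count of 0 called genes is reached by any split (35 of 35 in both comparisons, highest other 1), so splits say nothing about it. For the difference of the effects, 15 of 100 relabelings gave as many as 1198 genes (highest other 2792), and a count of 0 called genes is again reached by any of them (100 of 100, highest other 1).

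The clock genes with tubastatin are the first pattern weighed. With the adipocyte level as a covariate the whole clock list differed by -0.123 (SE 0.067) against -0.182 (SE 0.061) without it. The list averages members that move in opposite directions, so its level decides little. Of its 16 members 11 lay beyond 2 standard errors on the same side in both fits. For those members this argues against adipocyte share as the whole cause, though 2 standard errors is a loose limit with 8 libraries. A lower adipocyte share stays open as part of the cause. A glucocorticoid response to handling stays open as well, since its targets without Per1 went both ways, 2 of 11 higher and 2 lower at an unadjusted p under 0.05 (mean 0.057, SE 0.085). The hour at which fat was collected is not given, and a shift of that hour may move Arntl (0.561, SE 0.11) and Dbp (-0.75, SE 0.15) apart just as an effect of the drug on the clock would. The hour and the treatment cannot be told apart here.

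The second pattern is the cholesterol and interferon genes of AdKO. With the adipocyte level as a covariate, the cholesterol list differed by -0.471 (SE 0.119) and the interferon list by 0.455 (SE 0.131), which argues against adipocyte share as the whole cause. AdCre replicate 2 held transcripts of epididymal epithelium (Adam7 at 1.91, Gpx5 at 5.97, Lcn5 at 0.158 and Crisp1 at 0.197 FPKM). In AdCre replicate 3 Adam7 was at 5.57 and Epcam, a general epithelial gene, at 22.8. There Gpx5 was at 0.0803 and Lcn5 and Crisp1 at 0, so the epididymal reading of that library rests on Adam7. Adam7 was also read in vehicle replicates 1 (0.615) and 3 (0.358), and Crisp1 in AdKO replicates 1 (0.148) and 4 (0.139). Without AdCre replicates 2 and 3, which leaves 2 AdCre libraries, the lists differed by -0.601 (SE 0.254) and 0.499 (SE 0.143). With all libraries they differed by -0.612 and 0.467. Both stayed near their full size, which argues against that tissue as the whole cause. For cholesterol genes the argument is weak, since the difference is little over 2 standard errors with so few libraries. The share of immune cells was not tested as a cause of either difference and stays open. In AdKO the neutrophil (1.406), T and NK cell (0.485), B cell (0.509) and macrophage (0.335) lists averaged higher, and mast cells (-0.23) lower. A biological effect of the knockout stays open as a hypothesis, as do unlabelled differences between the animals, and chance is not excluded for the number of lists.

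The third pattern is lower adipocyte and higher matrix genes with tubastatin. Without vehicle replicate 2 the adipocyte difference was -0.144 (SE 0.1) against -0.294 with it, so the adipocyte part may rest on that library. If fewer adipocytes raised all other cell types alike, the 16 tested cell type lists would be higher. Their effects would also spread no more than in relabeled libraries. Their SD of 0.357 did not stand out (exact permutation p = 0.229), but an SD does not show direction. By direction the lists went both ways, with neutrophils at 0.774 (SE 0.185). T and NK cells (-0.495, SE 0.29) and B cells (-0.66, SE 0.414) were lower. No lower list lay beyond 2 standard errors, so this explanation stays open. Of 120 pairs of the 16 lists 19 lay beyond 2 standard errors, most clearly T and NK cells minus neutrophils (-1.269, SE 0.302). Relabeled libraries gave up to 37 such pairs, and as extreme a pair at exact permutation p = 0.314. Vehicle replicate 2 was also far from its group for lipogenesis (gap ratio 0.856), thermogenic genes (0.890) and the TCA cycle list (0.845).

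Elsewhere, 1 library of a group of 4 stood far from the rest by the ratio of its gap to the whole range. Among lists these were histone deacetylases (0.889) and interferon genes (0.853) in vehicle replicate 3, heat shock genes in tubastatin replicate 1 (0.871), lysosome genes (0.871) and Schwann cell genes (0.948) in tubastatin replicate 2 and macrophage genes in tubastatin replicate 3 (0.925). In the knockout cohort they were the clock list in AdCre replicate 2 (0.875), lymphatic genes in AdKO replicate 1 (0.837) and smooth muscle genes in AdCre replicate 1 (0.836). Among genes they were Hist1h1c in tubastatin replicate 1 (0.907), Fbxo2 in vehicle replicate 3 (0.839), Pfn2 in tubastatin replicate 4 (0.85) and Trbj1-6 in AdCre replicate 2 (ratio 1, the other 3 at 0). Trbj1-6 is a very short segment (chromosome 6, 41535554 to 41535606) with an AdCre mean of 0.219 FPKM, so its ratio rests on very few reads. In all, 16 of 228 groups were past the critical value, where chance gives about 11.

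The effects of drug and knockout differed by camera for 15 lists, as the mean tubastatin log2 fold change minus that of AdKO. The differences were -0.979 for T and NK cells, -1.169 for B and plasma cells, -0.435 for mesothelial cells, -0.393 for interferon genes and -0.214 for the clock list. They were 0.497 for cholesterol genes, 0.443 for matrix, 0.321 for immediate early, 0.282 for tubulins, 0.254 for lipogenesis, 0.214 for fatty acid oxidation, 0.196 for heat shock, 0.165 for the TCA cycle list, 0.145 for angiogenesis and 0.113 for oxidative phosphorylation. With an estimated correlation none of these lists kept the call, and their adjusted p with an estimated correlation was 0.25 to 0.849. By exact permutation of labels within both cohorts, 0 of 43 lists passed adjustment, and the smallest adjusted p was 0.0877, for tubulins (exact p = 0.00204). The cohorts differ in labelled genotype and labelled age, so these differences cannot be assigned to drug against knockout.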

How the results depend on the processing

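The voom fit and the fit without AdCre replicates 2 and 3 were chosen after the data were seen. Called genes for tubastatin against vehicle, 0 as reported, were 3 with no filter on low values, 1 with TPM, 8 with all 16 libraries sharing 1 spread, and 0 to 2 with a library left out. For AdKO against AdCre they were 2 with no filter, 43 with the shared spread, and 0 to 1 with a library left out. For the difference of effects they were 1 with no filter, 6 with array weights and 0 to 5 with a library left out. The other alternatives gave 0, voom included. Called lists went from 16 to 0 and from 17 to 0 with an estimated correlation, so those calls depend on the preset correlation. With a library left out they were 10 to 19 for tubastatin and 13 to 21 for AdKO, and 13 without AdCre replicates 2 and 3 together, 12 of them among the 17. With no filter on low values 46 lists were tested, and 19 were called for tubastatin and 23 for AdKO. Those gained in AdKO included the epididymis epithelium and testis germ cell lists. The B cell call in AdKO was also lost with a pseudocount of 0.1 and with median-of-ratios factors (16 lists each). The correlation of the effects ranged from -0.005 to 0.227 and the Hdac6 level difference with tubastatin from -0.042 to 0.026 with a library left out, positive without vehicle replicate 1 or 3 or tubastatin replicate 3. In AdKO that difference ranged from -0.3 without AdKO replicate 1 to -0.14 without AdKO replicate 2. Adipoq ranged from -0.201 to 0.068 with tubastatin and from -0.305 to 0.074 in AdKO. Apart from fewer libraries or more genes tested, the cause was not tested. Of 2264 alternative values of single genes and lists, 2179 kept direction and side of the threshold, 77 lost the call, 2 gained it and 6 turned direction. As 0 genes were called as reported, only lists could lose a call, and a gene kept its side by staying uncalled. The share kept therefore says little about single genes. The tally left out the shared spread, which called named genes such as Rdh10 (tubastatin) and Gata5 (AdKO).

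Replicate numbers showed no pairing in the drug cohort, where same-numbered libraries correlated at -0.104 to 0.018. In the knockout cohort they correlated at -0.232 to 0.33, which leaves pairing undecided there. With the replicate number as a block, 0 genes were called in both comparisons and for the difference, and 16 and 17 lists, where the tubulin call (tubastatin) and the B cell call (AdKO) gave way to others. AdKO replicates 1 (0.33) and 3 (0.206) correlated best with the AdCre library of their own number. AdKO replicates 2 and 4 and the tubastatin libraries did not match their own number best. Depth of 18234386 to 24776803 reads limits low genes such as Ucp1, at 0 to 21 reads.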

Other observations

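The comparison of vehicle with AdCre was not planned and was added after the data were seen, as were its alternatives, and the split count was fixed before it was run. The cohorts differ in labelled genotype and in labelled age (25 and 28 weeks), though the series' design line puts the drug cohort at about 28 weeks too, so no cause can be assigned. B and plasma cell genes were higher in vehicle than in AdCre (mean log2 fold change 2.45) and so were T and NK cell genes (1.18) and mast cell genes (1.07), while lipogenesis (-0.61), adipocyte identity (-0.55), endothelial (-0.56) and cholesterol genes (-0.52) were lower. These lists passed camera, with adjusted p = 0.612 with an estimated correlation for each. Limma-trend called 1175 genes, 565 higher and 610 lower. In 2 of 35 splits as many were called, with 1384 as the highest other, so chance is not excluded. The count was 49 without AdCre replicate 4, 78 without vehicle replicate 1, 99 without vehicle replicate 3, 176 without vehicle replicate 4 or AdCre replicate 2, 190 without AdCre replicate 3 and 2660 without vehicle replicate 2.

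Hdac6 itself was among the genes with the smallest p in that comparison, at 1.58 ± 0.167 FPKM in vehicle and 4.17 ± 0.450 in AdCre (SD, n = 4, limma SE 0.0841 on the log2 scale, adjusted p = 0.0045), 62% lower. The labelled genotype, the labelled age and the cohort all differ between these groups and were not separated.

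With 1 spread shared by all 16 libraries, the 8 genes called with tubastatin included Socs3, Ahr, which encodes a ligand-activated transcription factor (log2 fold change 0.66, 4.47 ± 0.714 against 2.46 ± 0.365 FPKM), and the proteasome subunit gene Psmd11 (0.40). Those called in AdKO included Cox7a2 (-0.46) of the oxidative phosphorylation list, and the T cell genes Cxcr6 (1.86) and Tcrg-C1 (1.34). Ndufb9 (-0.61), Ndufb4 (-0.43) and Atp5k (-0.84), genes of the same process outside that list, were called as well. With the spread of their own cohort none of the genes named here passed. Their limma adjusted p was then 0.153 to 0.179 with tubastatin and 0.202 to 0.203 in AdKO. The median SE was 0.0894 with tubastatin and 0.117 in AdKO, so a shared spread can understate the error in AdKO. Sharing it moved the genes at an unadjusted p under 0.05 from 1452 to 2119 in AdKO and from 1597 to 1218 with tubastatin. Socs3 in AdKO differed by 0.141 (SE 0.143).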
